A study of Homo sapiens with 6 samples.

How the data were processed

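Gene expression was measured by RNA-seq in 6 libraries of A549, a cell line derived from a human lung adenocarcinoma. Per the labels, 3 libraries came from cells given DMSO, the solvent control, and 3 from cells given 1.0 µM of the compound S541, also named 5n, for 48 h. The series' design text calls the profiles retinal, while the label of each sample names A549, and the sample labels were followed. The library titles give the group and a replicate number. The labels do not say whether the replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical.

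The deposited table of all genes lists 58302 genes with Ensembl identifiers, names, gene types and loci. Its whole-number counts per gene were made by the authors and were used here as deposited. The aligner, the counting tool and the use of strand in counting are not given in the sources used here. The genome build is hg38 and the comparison was made with edgeR, per the submitters' processing notes. Of the gene identifiers, 97.1% had the chromosome, start and end of GENCODE release 29, and that annotation was used to find genes whose exons overlap those of another gene. The FPKM values in the same table, per the file headers, follow from the deposited counts, the gene length and the library total. In 10632 genes with at least 100 counts in every library, FPKM times the library total divided by the count differed between libraries by at most 0.000905%. The authors' deposited comparison table holds a log2 fold change, a p-value and an adjusted p-value (Q-value) for 28099 genes, those with at least 2 counts over the 6 libraries. The 302 genes that the authors deposited as differential are exactly those with an absolute log2 fold change of at least 1, an unadjusted p-value under 0.05 and a mean FPKM of at least 1 in a group. The authors also deposited a sheet with the FPKM of 37 genes, chosen by a rule that is not given in the sources used here. All value columns matched a library by its title.

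Total counts were 14927663, 17044139 and 16592011 in DMSO replicates 1 to 3 and 13956648, 15794403 and 15644627 in S541 replicates 1 to 3. The counts were fitted with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr as the filter on low counts and group as the only term, which left 15847 genes. The quasi-likelihood test (glmQLFit and glmQLFTest) gave 2-sided p-values, which were adjusted over all tested genes by the Benjamini-Hochberg method. A gene is said to have risen or fallen where its adjusted p-value was under 0.05. Fold changes are log2 values of S541 over DMSO with their standard errors (SE), and levels are CPM (the cpm function of edgeR, with TMM scaling), as mean ± SD over 3 libraries. A common biological coefficient of variation of 0.163 was estimated.

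For groups of genes, 38 lists of pathway, complex and cell type genes were tested with limma 3.58.1 (camera on log2 CPM) at a preset correlation of 0.01, where at least 5 members were tested, with Benjamini-Hochberg adjustment over the 37 lists that had them. The number of members that rose or fell is given as adjusted over all genes, and again as adjusted over the list alone. Terms of Gene Ontology and KEGG in the deposited annotation, with 10 to 500 tested genes, were tested in the same way. The genes named in the text are the 10 highest and the 10 lowest fold changes past the threshold with at least 10 CPM in the higher group, no overlap between the groups' libraries and an approved symbol that is not a pseudogene's. For each list they are also up to 4 members past the threshold by size of change with at least 1 CPM in the higher group, or the 2 most abundant members where none passed. CYP1A1, CYP1B1, CDKN1A, DDIT3 and TFAM are named whatever their values. Some genes that this rule names are not reported. Other genes are named only to complete a group and were chosen after their values were seen. The groups, the tests, the lists, the rule for named genes and the alternatives, except those said below to be added, were fixed before the data were examined.

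The functions were tested on simulated data: counts for 15847 genes were drawn from the real means, library sizes and dispersions, with 200 genes changed. The filter on low counts then left 15590 of the simulated genes. For S541 against DMSO, the quasi-likelihood test recovered 17.9% of genes changed 1.5-fold, 86.6% of those changed 2-fold and 100% of those changed 4-fold, none in the wrong direction, with 12 false calls. The share recovered at 1.5-fold belongs to this setting, with 200 genes changed. In the real libraries 1298 genes changed, with a median absolute log2 fold change of 0.665. A planted list was recovered, and 0 of 200 random lists passed. The simulated genes were drawn independently of each other. The 0 therefore does not cover lists whose genes vary together, as in the real libraries (estimated correlation 0.675 for the mRNAs encoded in mitochondrial DNA).

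Alternatives were DESeq2's size factors or upper-quartile scaling, no filter on low counts or at least 1 CPM in 3 libraries, the replicate number as a block, DESeq2 1.42.0, limma-voom, the exact test of edgeR, a test against a 1.2-fold change (glmTreat), an estimated correlation or the fry test for the lists, and each library left out in turn. Libraries left out 1 at a time are named by group and replicate number, as DMSO 1. A range beside them is the lowest and highest adjusted p-value over the fits that ended the call. Robust estimation of the spread, and leaving out genes whose counts differed 4-fold or more within a group, were added after seeing the data. The deposited tables split by direction hold the same 302 genes and were not used further.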

Results

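The series compared A549 lung adenocarcinoma cells after 48 h with 1.0 µM of the compound S541 with cells given DMSO, in a study whose title concerns mitochondrial homeostasis. There were 3 libraries per group. Total counts ranged from 13956648 to 17044139 per library. *MT-CO1* was the most abundant gene in every library, with 1.17 to 1.49% of the counts, and transcripts of the mitochondrial genome made up 5.32, 4.56 and 5.14% of the counts in the DMSO libraries and 4.38, 4.56 and 4.78% in the S541 libraries. On the first principal component of log2 CPM (38.9% of the variance) the groups separated, with DMSO libraries from −27.6 to −26.9 and S541 libraries from 26.0 to 29.9. DMSO replicate 2 and S541 replicate 3 lay apart from the others on the second component (21.4%), at −34.4 and −20.5. No pair of libraries agreed within sampling noise, with a chi-square per degree of freedom of at least 11.99.

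After S541, transcripts of the stress-associated and secreted factors *IL11*, *STC2* and *SERPINE2*, the AP-1 subunit *FOSL1* and the phosphatase *DUSP4*, which acts on MAP kinases, were among the genes that rose. Those that fell included the prion protein gene *PRNP*, the alkaline phosphatase *ALPG*, the sodium-chloride cotransporter *SLC12A3* and the epithelial transcription factor *EHF*. Of 15847 genes tested, 1298 changed, 637 higher and 661 lower in S541, and 325 of them by 2-fold or more (192 higher, 133 lower). All 1298 had no overlap between the libraries of the groups, as did 4926 of the tested genes, where chance gives 10%. At an unadjusted p-value under 0.05 there were 3933 genes. Leaving out 1 library lowered the number of changed genes from 1298 to 628 without DMSO replicate 1, 398 without DMSO replicate 3, 375 without S541 replicate 1, 349 without S541 replicate 2 and 550 without S541 replicate 3. Without DMSO replicate 2 it was 1330 (376 by 2-fold or more). The number changed 2-fold or more fell from 325 to 196 without DMSO replicate 3, and to 187, 162 and 209 without S541 replicates 1, 2 and 3. Of 99 named genes past the threshold, 45 stayed past it in each of the 6 fits with a library left out, and 54 with glmTreat against a 1.2-fold change, a stricter null.

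*DHRS2* (ENSG00000100867, chromosome 14, 23630115 to 23645639), a short-chain dehydrogenase, rose from 3.72 ± 0.708 CPM (SD, n = 3) to 25.9 ± 4.39 CPM, a log2 fold change of 2.80 (SE 0.20, adjusted p = 0.000871, edgeR). The protease inhibitor *SERPINE2* (ENSG00000135919, chromosome 2, 223975112 to 224039319) rose by 2.69 (SE 0.21), *SPOCD1* by 2.41 (SE 0.14), and the cytokine *IL11* from 11.4 ± 4.84 to 56.9 ± 2.39 CPM. *FOSL1* (ENSG00000175592) rose from 26.2 ± 3.32 to 106 ± 11.4 CPM, *PHLDA1* from 32.0 ± 0.986 to 111 ± 6.19 CPM, *DUSP4* from 31.3 ± 3.62 to 102 ± 3.46 CPM and *STC2* from 37.9 ± 8.52 to 128 ± 13.3 CPM. *CD68* (log2 fold change 1.94) and *TOMM6* (1.85) also rose, but other gene models cover 85.8% and 100% of their exons, so the gene that their reads came from is uncertain. Among the falls, *PRNP* (ENSG00000171867, chromosome 20, 4686236 to 4701590) went from 45.6 ± 3.69 to 11.5 ± 1.23 CPM, *ALPG* (ENSG00000163286, chromosome 2, 232406843 to 232410714) from 1553 ± 51.9 to 432 ± 41.7 CPM, and *SLC12A3* from 159 ± 7.58 to 48.1 ± 6.74 CPM. *ALPG* has near-identical paralogs, so the division of reads among them is uncertain. *FAM167B*, *SERTAD4*, *PRSS56* and *RARRES2* fell by 1.82, 1.71, 1.65 and 1.59 on the log2 scale. *SLC6A12* fell by 2.89, with DMSO libraries spread widely (41.0 ± 32.0 CPM), and *EHF* by 1.89 and *TSKU* by 1.63. These last 3 genes and *TOMM6* lost their calls without DMSO replicate 1 (adjusted p = 0.0712 for *SLC6A12*, 0.0639 for *EHF*, 0.0657 for *TSKU* and 0.0981 for *TOMM6*), S541 replicate 1 (0.102, 0.096, 0.0987 and 0.111) or S541 replicate 2 (0.134, 0.102, 0.105 and 0.113). Without DMSO replicate 3, *SLC6A12* (0.0916), *EHF* (0.0894) and *TOMM6* (0.122) did, and without S541 replicate 3, *SLC6A12* (0.107) and *EHF* (0.0933). With no filter on low counts *SLC6A12* (0.0545) and *TOMM6* (0.0621) lost their calls too, and with limma-voom *SLC6A12* (0.12), *EHF* (0.0641) and *TOMM6* (0.0528). Robust estimation of the spread, chosen after seeing the data, ended all 4 (0.09 for *SLC6A12*, 0.0563 for *EHF*, 0.0537 for *TSKU* and 0.0835 for *TOMM6*). The other 16 of the 20 genes named by size of change under the fixed rule passed in each of the fits with a library left out.

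**Figure D1:**
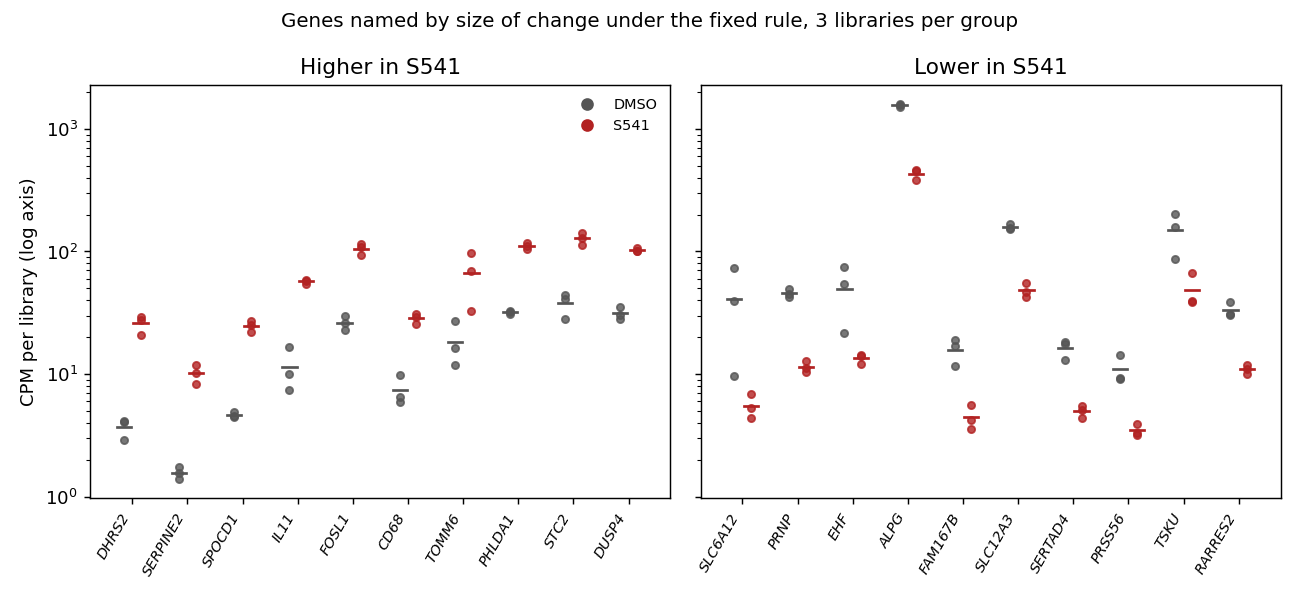
CPM in each library (log axis) for the 10 genes with the highest and the 10 with the lowest log2 fold change by the fixed rule, with DMSO in grey, S541 in red, 1 point per library and a bar at the mean of 3. For *PRNP* the DMSO libraries (mean 45.6 CPM) lie above the S541 libraries (mean 11.5 CPM), while the DMSO libraries of *SLC6A12* spread widely.

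Few transcripts of the mitochondrial energy machinery changed. Of the 13 mRNAs encoded in mitochondrial DNA, *MT-CO3* (5909 ± 251 to 4078 ± 208 CPM, log2 fold change −0.53, SE 0.07, adjusted p = 0.00720) and *MT-CO2* (−0.38, adjusted p = 0.0470), both subunits of cytochrome c oxidase, fell and 11 did not pass. Adjusted over the list alone, 3 fell. *NDUFB1* (−0.59) fell among 37 nuclear complex I subunits, 1 also when adjusted over the list alone. No member passed among 39 nuclear subunits of complexes II to V (*ATP5F1B* 0.08, SE 0.13, and *ATP5F1E* −0.05, SE 0.09) or among 76 mitochondrial ribosomal proteins (*MRPS30* 0.12, *MRPS34* −0.05), either over all genes or adjusted over the list alone. In the TCA cycle list, pyruvate carboxylase (*PC*) fell from 194 ± 7.69 to 98.1 ± 7.04 CPM and the other 21 did not pass. The mitophagy kinase *PINK1* fell from 230 ± 9.98 to 130 ± 18.4 CPM, the single change among 18 mitophagy genes, although other gene models, mostly on the other strand, overlap 41.7% of its exons. *TFB2M*, a mitochondrial transcription factor, rose by 0.59 among 27 dynamics and biogenesis genes, whereas *TFAM* had a log2 fold change of 0.02 (SE 0.14, adjusted p = 0.952). In the last 3 lists the same numbers passed when adjusted over the list alone. As sets, these lists did not pass, with camera adjusted p = 0.0633 for the mtDNA mRNAs, 0.557 for complex I, 0.787 for complexes II to V, 0.403 for the ribosomal proteins, 0.301 for the TCA cycle, 0.0952 for dynamics and 0.744 for mitophagy. The mtDNA list passed without DMSO replicate 2 (adjusted p = 0.00501) or S541 replicate 3 (0.038) and with no filter on low counts (0.0351), and the dynamics list without S541 replicate 3 (0.0428). *MT-CO3*, *PC* and *PINK1* passed without any single library, while with 1 library left out these calls ended: *MT-CO2* without DMSO 1 or 3 or S541 1 or 2 (0.12 to 0.167), *NDUFB1* without DMSO 1 or 3 or S541 1 or 2 (0.0683 to 0.089) and *TFB2M* without DMSO 1 or 3 or S541 1, 2 or 3 (0.0502 to 0.11). With no filter on low counts the calls of *MT-CO2* (0.079) and *TFB2M* (0.0514) ended as well, and under upper-quartile scaling that of *MT-CO2* (0.05).

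A few mitochondrial import, chaperone and protease genes rose. *TOMM6*, the import channel *TOMM40* (0.56), *GRPEL1* (0.52) and the chaperonin *HSPD1* (0.31, from 637 ± 16.4 to 791 ± 54.4 CPM) rose among 30 members, 5 when adjusted over the list alone, and none fell. The set passed upward (camera adjusted p = 0.0346) but had an adjusted p = 0.577 with an estimated correlation. Its call was also lost without DMSO replicate 1 (adjusted p = 0.0585), DMSO replicate 3 (0.177) or S541 replicate 3 (0.0876) and with fry (0.157). Single genes lost their calls, *TOMM6* without DMSO 1 or 3 or S541 1 or 2 (0.0981 to 0.122), *TOMM40* without DMSO 1 or 3 or S541 2 or 3 (0.121 to 0.148), *GRPEL1* without DMSO 1 or 3 or S541 1, 2 or 3 (0.0616 to 0.103) and *HSPD1* without DMSO 1, 2 or 3 or S541 1, 2 or 3 (0.0685 to 0.162). All 4 also lost them with no filter on low counts (0.0621, 0.0884, 0.0567 and 0.0913), *TOMM6* (0.0528) and *TOMM40* (0.0527) with limma-voom, *HSPD1* with DESeq2 size factors (0.0525) and the exact test (0.0625), and *TOMM6* with robust estimation of the spread (0.0835).

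Stress-response genes rose in several lists. Of 43 integrated stress response genes, which include targets of ATF4, 8 rose and 3 fell (13 and 4 adjusted over the list alone). *STC2*, *GDF15* (1.34) and *DDIT3* (7.35 ± 2.08 to 15.2 ± 3.21 CPM) rose, although other gene models, mostly on the other strand, overlap 39.6% of the exons of *DDIT3*. The glycine transporter *SLC6A9* (−1.05) fell, as did the cysteine-synthesis enzyme *CTH* (−1.01) and *JDP2* (−0.95). This set passed upward (camera adjusted p = 0.0187) with an adjusted p = 0.362 with an estimated correlation, and its call was lost without DMSO replicate 1 (adjusted p = 0.0764). Among 26 genes of the endoplasmic reticulum chaperones and unfolded protein response, the chaperone *HSPA5* (997 ± 24.6 to 1454 ± 18.8 CPM) and the sensor *ERN1* (0.64) rose, 3 adjusted over the list alone (camera adjusted p = 0.00583, and adjusted p = 0.173 with an estimated correlation). Cytosolic heat shock genes had 8 of 18 members higher, *DNAJB4* (0.66), *HSPA1B* (0.63), *HSPA1A* (0.52) and *HSP90AB1* (2132 ± 36.6 to 2817 ± 120 CPM) among them, and *HSPB8* lower. Adjusted over the list alone the numbers were 11 and 1, and the set had a camera adjusted p = 0.000121 and an adjusted p = 0.313 with an estimated correlation. *HSPA1A* and *HSPA1B* are near-identical copies, so the split of reads between them is uncertain, and another gene model on the same strand overlaps 36.5% of the exons of *HSPA1B*. The metallothioneins *MT1X* (1.01) and *MT1E* (0.77), which bind zinc and also resemble each other, rose among 7 tested metallothionein and zinc transporter genes, 2 also when adjusted over the list alone (camera adjusted p = 0.0407, and adjusted p = 0.268 with an estimated correlation). That set's call was lost without DMSO replicate 1 (0.0801), 2 (0.0538) or 3 (0.0537) or S541 replicate 1 (0.0614). In the hypoxia list, *STC2* and the carbonic anhydrase *CA12* (1.06) rose among 29 members, 4 when adjusted over the list alone. The hypoxia set passed upward (camera adjusted p = 0.00487, and adjusted p = 0.654 with an estimated correlation), but not without DMSO replicate 2 (0.0894) or S541 replicate 1 (0.0626), nor with fry (0.241). Of the genes named here, *STC2*, *GDF15*, *SLC6A9*, *HSPA5*, *HSPA1A*, *HSPA1B* and *CA12* passed without any single library. Calls ended for *DDIT3* without DMSO 2 or 3 or S541 1, 2 or 3 (0.0557 to 0.13), *CTH* without DMSO 3 or S541 1 or 2 (0.0519 to 0.0565), *JDP2* without DMSO 1 or S541 1, 2 or 3 (0.0583 to 0.126) and *ERN1* without DMSO 1 or 3 or S541 1, 2 or 3 (0.0595 to 0.0994). They also ended for *DNAJB4* without DMSO 3 or S541 1 or 2 (0.0564 to 0.069), *HSP90AB1* without DMSO 3 or S541 1 or 2 (0.0502 to 0.0707), *HSPB8* without DMSO 1 or 3 or S541 1, 2 or 3 (0.0816 to 0.114) and *MT1X* without DMSO 1, 2 or 3 or S541 1 or 3 (0.0626 to 0.132). The same was true of *MT1E* without DMSO 1 or 3 or S541 1, 2 or 3 (0.0749 to 0.1). No filter on low counts ended those of *DDIT3* (0.0634), *JDP2* (0.0607), *HSPB8* (0.0618), *MT1X* (0.0752) and *MT1E* (0.0571), and limma-voom that of *MT1X* (0.058).

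Many DNA replication genes fell. Of 48 genes of the G1/S transition and DNA replication, 15 fell and none rose, with a median log2 fold change of −0.32. The helicase subunit *MCM5* went from 222 ± 15.3 to 117 ± 5.76 CPM (−0.92, SE 0.09, adjusted p = 0.00239, edgeR), *E2F1*, a transcription factor of S-phase entry, from 139 ± 5.06 to 89.4 ± 5.65 CPM, and the G1/S cyclins *CCNE2* and *CCNE1* fell by 0.80 and 0.68. Other gene models, on the other strand, overlap 37.1% of the exons of *CCNE2*. Adjusted over the list alone, 24 members fell. The set had a camera adjusted p = 2.17e-08, which held in every fit with a library left out, and an adjusted p = 0.173 with an estimated correlation. *MCM5* and *E2F1* passed without any single library. *RMI2* (−0.57) and *FANCC* (−0.55) fell among 32 genes of homologous recombination and the Fanconi pathway, 2 also when adjusted over the list alone (camera adjusted p = 0.0456, and adjusted p = 0.648 with an estimated correlation). That call was lost without DMSO replicate 1 (0.171) or 3 (0.0869) or S541 replicate 1 (0.055) or 3 (0.209), and with fry (0.241). In contrast, 5 of 57 G2/M and mitosis genes rose and none fell. They were *CKS2* (106 ± 3.54 to 166 ± 18.2 CPM), the mitotic kinases *AURKA* (0.63) and *BUB1* (0.49), cyclin B1 (*CCNB1*, 0.51) and the spindle checkpoint gene *MAD2L1* (0.39). Adjusted over the list alone, 11 rose and 2 fell, and the set did not pass (camera adjusted p = 0.0506) except under upper-quartile scaling (0.0456), at a minimum of 1 CPM in 3 libraries (0.0465) or without S541 replicate 3 (0.038). *TUBB2A* (0.47) rose and *TUBB* (−0.41) fell among 14 tubulin genes (1 each adjusted over the list alone), which have similar sequences (camera adjusted p = 0.479). Of 15 core histone genes, *HIST2H2AA3* (0.94), which has a near-identical copy, rose, 3 adjusted over the list alone (camera adjusted p = 0.0720). The histone set passed without DMSO replicate 1 (0.00136) and at a minimum of 1 CPM in 3 libraries (0.043). Of the mitosis genes named, *CKS2* passed without any single library. Calls ended for *CCNE2* without DMSO 1 or 3 or S541 1, 2 or 3 (0.0667 to 0.0975), *CCNE1* without S541 2 (0.0618), *RMI2* without DMSO 1 or 3 or S541 1, 2 or 3 (0.0571 to 0.0825) and *FANCC* without DMSO 3 or S541 1, 2 or 3 (0.054 to 0.0744). They also ended for *AURKA* without DMSO 3 or S541 1, 2 or 3 (0.0618 to 0.0993), *BUB1* without DMSO 1 or 3 or S541 1 or 2 (0.0564 to 0.0801), *CCNB1* without DMSO 1 or 3 or S541 2 or 3 (0.0617 to 0.077) and *MAD2L1* without DMSO 1, 2 or 3 or S541 1, 2 or 3 (0.0735 to 0.141). The same was true of *TUBB2A* without DMSO 2 or 3 or S541 1, 2 or 3 (0.0713 to 0.14), *TUBB* without DMSO 1 or 3 or S541 1 or 2 (0.0617 to 0.103) and *HIST2H2AA3* without DMSO 3 or S541 1, 2 or 3 (0.0598 to 0.0686). No filter on low counts ended those of *MAD2L1* (0.0833) and *TUBB2A* (0.0776).

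Some targets of p53 rose, while 20 of 35 had a fold change above 0 and the set did not pass. *GADD45A* (15.6 ± 3.00 to 39.6 ± 3.32 CPM), *GDF15* and the death receptor *FAS* (1.04) were among 8 of 35 that rose, as was the cyclin-dependent kinase inhibitor *CDKN1A* (76.0 ± 5.87 to 125 ± 17.6 CPM, 0.71, adjusted p = 0.0146, edgeR). The phosphatase *PPM1D* (−0.59) fell, and 9 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.0811, and 0.00288 with fry). *CDKN1A* lost its call without DMSO replicate 3 (adjusted p = 0.064) or S541 replicate 1 (0.0532). Of 28 genes of the BCL2 family and caspases, *BOK* (−0.51) fell, 1 also when adjusted over the list alone (camera adjusted p = 0.962). Other calls ended for *FAS* without DMSO 1 or 3 or S541 1, 2 or 3 (0.0649 to 0.0832), *PPM1D* without DMSO 1 or 3 or S541 1 or 2 (0.0518 to 0.0794) and *BOK* without DMSO 1, 2 or 3 or S541 1 or 2 (0.0523 to 0.12), and for *BOK* with no filter on low counts (0.0604).

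Several lipid synthesis genes fell. The regulator *SREBF1* went from 177 to 97.7 CPM (−0.86, SE 0.09, adjusted p = 0.00410, edgeR), the desaturase *SCD* from 1078 ± 15.2 to 654 ± 14.1 CPM and *FADS1* from 514 ± 50.4 to 358 ± 29.6 CPM, while the fatty acid carrier *FABP5* (0.54) rose. In all, 5 of 17 fatty acid synthesis genes fell and 1 rose (9 and 1 adjusted over the list alone), with a camera adjusted p = 0.00324 and an adjusted p = 0.173 with an estimated correlation. Of 25 genes of cholesterol synthesis, 5 fell and 1 rose (10 and 1 adjusted over the list alone). *FDPS* (−0.54), *MVK* (−0.54), *ACAT2* (−0.52) and the regulator *SREBF2* (−0.52) fell. Other gene models, *TCP1* among them, overlap 52.3% of the exons of *ACAT2*. This set had a camera adjusted p = 0.000121 and an adjusted p = 0.267 with an estimated correlation, and both lipid sets passed in every fit with a library left out, as did *SREBF1* and *SCD*. *HADH* (−0.57) fell among 23 fatty acid oxidation genes and the kinase *HK2* (0.77) rose among 21 of glycolysis, with 1 lower, and 2 higher and 1 lower, adjusted over the list alone (camera adjusted p = 0.301 and 0.415). Single calls ended for *FADS1* without DMSO 3 or S541 1, 2 or 3 (0.0527 to 0.0978), *FABP5* without DMSO 1, 2 or 3 or S541 1, 2 or 3 (0.0523 to 0.117), *FDPS* without DMSO 1 or S541 1, 2 or 3 (0.0612 to 0.0978) and *MVK* without DMSO 1 or 3 or S541 1, 2 or 3 (0.0686 to 0.135). They also ended for *ACAT2* without S541 1 (0.0593), *SREBF2* without DMSO 3 or S541 1 or 2 (0.0701 to 0.0867), *HADH* without DMSO 3 or S541 1, 2 or 3 (0.0578 to 0.0855) and *HK2* without DMSO 1 or 3 or S541 1, 2 or 3 (0.0595 to 0.121). With no filter on low counts those of *FABP5* (0.0774), *MVK* (0.0791) and *HK2* (0.0616) ended too.

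Several inflammatory and matrix genes rose. Of 24 genes of cytokines and NF-kB, 9 rose and 1 fell (11 and 3 adjusted over the list alone). *IL11* led, followed by the chemokine *CXCL8* (1.94 ± 0.529 to 9.58 ± 2.01 CPM) and, at low levels, *IL1B* (0.741 ± 0.306 to 2.80 ± 0.321 CPM) and *IL1A* (0.955 ± 0.109 to 2.93 ± 0.621 CPM). The inhibitor of NF-kB *NFKBIA* (−0.97) was the member that fell. The set had a camera adjusted p = 5.45e-05, past the threshold in every fit with a library left out, and an adjusted p = 0.173 with an estimated correlation. Among 22 genes of mesenchymal transition and matrix, 5 rose and none fell (9 and 0 adjusted over the list alone), including the repressor *SNAI1* (6.57 ± 1.00 to 13.8 ± 0.738 CPM) and *THBS1* (1.03). That set also passed in every such fit (camera adjusted p = 0.00148, and adjusted p = 0.173 with an estimated correlation). Epithelial junction and keratin genes had 6 of 18 members lower and 1 higher (8 and 2 adjusted over the list alone). *KRT18* went from 993 ± 44.0 to 641 ± 53.3 CPM, *KRT8* from 1794 ± 119 to 1273 ± 60.2 CPM, and *CLDN7* (−0.80) and *TJP3* (−0.71), genes of tight junctions, fell. The epithelial set passed downward (camera adjusted p = 0.0407, and adjusted p = 0.267 with an estimated correlation), but not without DMSO replicate 2 (0.084) or 3 (0.0569) or S541 replicate 1 (0.0614) or 3 (0.0575), nor with no filter on low counts (0.0698). *IFI6* (−0.51) was the single change among 31 interferon-stimulated genes, 1 also when adjusted over the list alone (camera adjusted p = 0.557). *IL11*, *CXCL8*, *NFKBIA*, *SNAI1*, *THBS1*, *KRT18* and *CLDN7* passed without any single library. Calls ended for *IL1B* without S541 2 (0.0513), *IL1A* without DMSO 3 (0.0535), *KRT8* without S541 1 or 2 (0.0631 to 0.0642) and *TJP3* without DMSO 1 or 3 or S541 1 or 2 (0.0571 to 0.0718). They also ended for *IFI6* without DMSO 1 or 3 or S541 1, 2 or 3 (0.0595 to 0.0872).

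Several genes of ribosome assembly rose. Of 32 nucleolar ribosome biogenesis genes, 9 rose and none fell (19 and 0 adjusted over the list alone), and all 32 fold changes were above 0. *DDX10* (0.69), *RRP9* (0.61), *RRP12* (67.7 ± 4.09 to 103 ± 3.31 CPM) and *NOP16* (0.54) were among them. Of these, *RRP12* passed without any single library. The calls ended for *DDX10* without DMSO 1 or 3 or S541 1 or 2 (0.064 to 0.0973), *RRP9* without DMSO 1 or 3 or S541 1, 2 or 3 (0.0828 to 0.144) and *NOP16* without DMSO 3 or S541 2 or 3 (0.0522 to 0.0655). That of *RRP9* also ended with DESeq2 size factors (0.0501) and with no filter on low counts (0.0912). The set had a camera adjusted p = 3.86e-08, past the threshold in every fit with a library left out, and an adjusted p = 0.267 with an estimated correlation. Its member *MYC* had a log2 fold change of 1.15 and did not pass (adjusted p = 0.569, edgeR). The level of *MYC* differed 4-fold or more between libraries of the same group. None of 74 cytosolic ribosomal proteins passed over all genes or adjusted over the list alone (*RPL37* −0.06, SE 0.21, *RPS18* −0.13, SE 0.16, camera adjusted p = 0.415, but 0.047 without S541 replicate 3), nor did any of 19 nucleotide synthesis genes (*PAICS* 0.27, SE 0.20, *IMPDH2* 0.11, SE 0.13, camera adjusted p = 0.809).

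**Figure D2:**
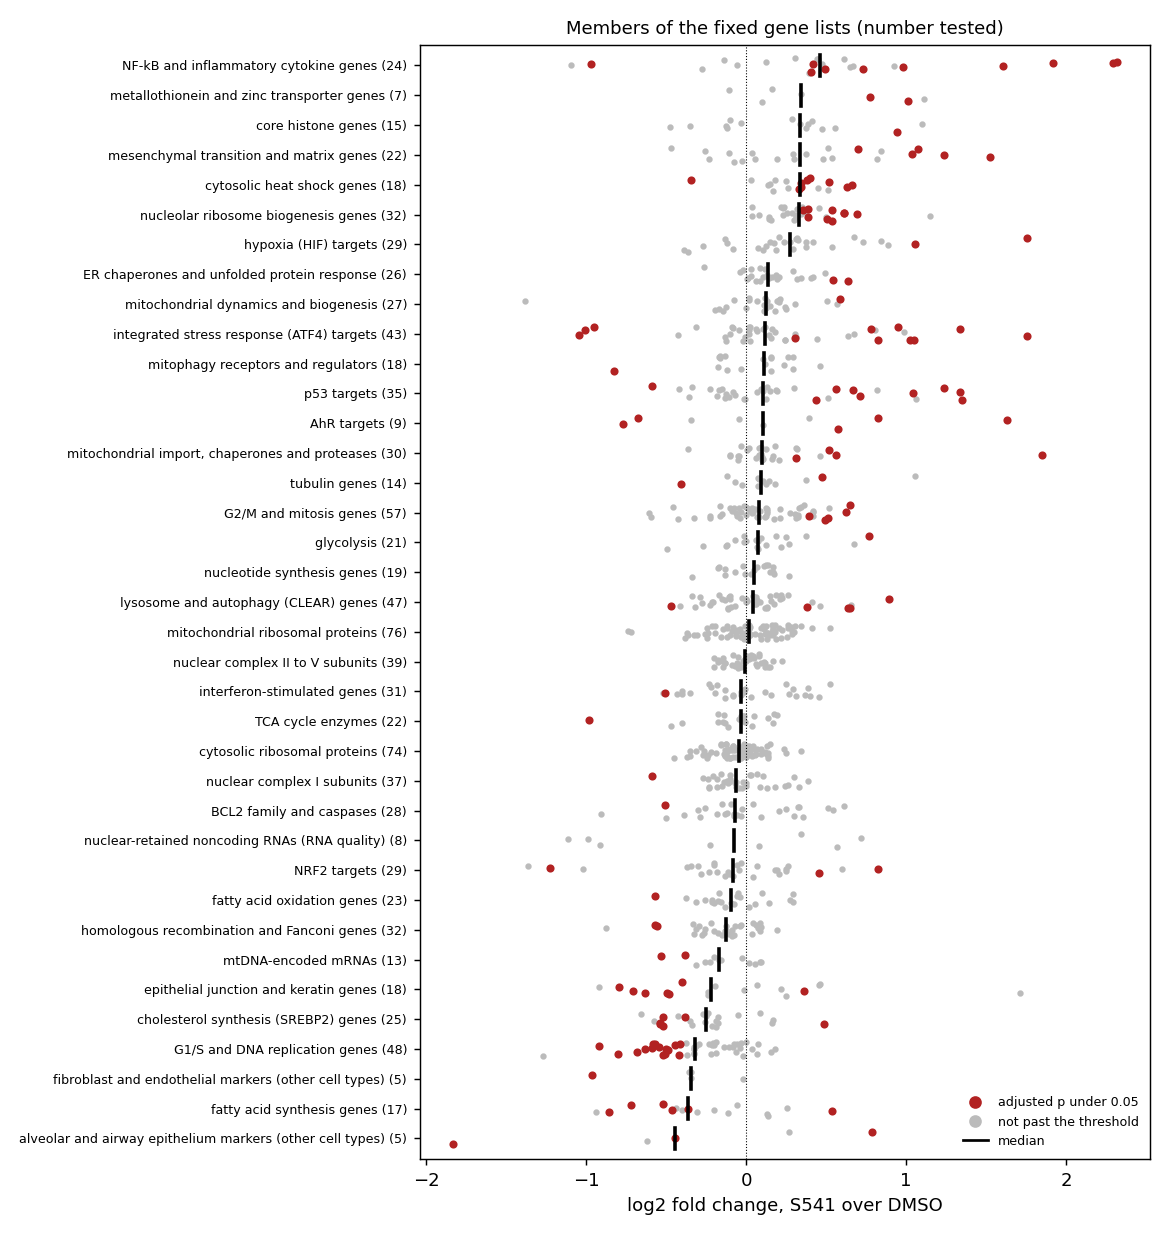
Log2 fold change (S541 over DMSO) of each tested member of the fixed gene lists, 1 point per gene, red where the adjusted p-value was under 0.05 and grey otherwise, with a black bar at the list's median and the number tested in parentheses. The median of the G1/S and DNA replication list lies at −0.32 and that of the nucleolar ribosome biogenesis list at 0.33.

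Genes of xenobiotic and antioxidant responses changed in both directions. The aryl hydrocarbon receptor target *CYP1A1* rose from 1.72 ± 0.511 to 5.32 ± 1.22 CPM (1.63, SE 0.28, adjusted p = 0.0158, edgeR) and the receptor *AHR* from 37.5 ± 3.89 to 66.5 ± 5.69 CPM, whereas *AHRR* (−0.67) and *ALDH3A1* (−0.77) fell and *CYP1B1* did not pass (0.39, SE 0.18, adjusted p = 0.228). In that list 3 of 9 rose and 2 fell (3 and 3 adjusted over the list alone, camera adjusted p = 0.670), and the call of *CYP1A1* was lost without DMSO replicate 3 (adjusted p = 0.0538), S541 replicate 1 (0.0544) or S541 replicate 3 (0.0534). Of 29 NRF2 targets, the cystine transporter *SLC7A11* (0.82) and *SRXN1* (0.45) rose and *AKR1C3* (227 ± 53.5 to 97.2 ± 5.24 CPM) fell, with 3 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.557). Other gene models, mostly on the same strand, overlap 32.3% of the exons of *AHR*. Another gene model covers 85% of the exons of *SRXN1*, and *AKR1C3* has close paralogs. Lysosome and autophagy genes had 4 of 47 higher and 1 lower (6 and 1 adjusted over the list alone, camera adjusted p = 0.557). The protease *CTSL* (84.5 ± 8.55 to 157 ± 15.9 CPM), *NEU1* (0.65) and the cholesterol transporter *NPC1* (0.64) rose, and the transcription factor *TFEB* (−0.47) fell. *AHR*, *AHRR*, *AKR1C3*, *CTSL* and *NPC1* passed without any single library. Further calls ended for *ALDH3A1* without DMSO 1 or 3 or S541 1, 2 or 3 (0.0607 to 0.0844), *SLC7A11* without S541 1 or 2 (0.0629 to 0.0665), *SRXN1* without DMSO 1 or 3 or S541 1, 2 or 3 (0.0515 to 0.097) and *NEU1* without DMSO 3 (0.0558). They also ended for *TFEB* without DMSO 1, 2 or 3 or S541 1, 2 or 3 (0.0798 to 0.143), and with no filter on low counts for *SRXN1* (0.0523) and *TFEB* (0.0913).

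Among markers of other cell types, most were too low to test. Of 18 alveolar and airway epithelium markers, 5 were tested, *MUC5AC* (0.79) rose and *AQP5* (2.67 ± 0.296 to 0.745 ± 0.0491 CPM) and *ABCA3* (−0.44) fell, with 1 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.301, and 0.00754 with fry). *CD68* rose among 3 tested leukocyte markers, 1 also when adjusted over the list alone, too few for a set test. *PDGFRB* (−0.96) fell among 5 tested fibroblast and endothelial markers, 1 also when adjusted over the list alone (camera adjusted p = 0.147, but 0.044 without S541 replicate 2). The call of *PDGFRB* was lost in each fit with a library left out, without DMSO 1, 2 or 3 or S541 1, 2 or 3 (0.068 to 0.164), and under upper-quartile scaling (0.0501), no filter (0.0881), limma-voom (0.058) and glmTreat, and that of *ABCA3* without DMSO 3 or S541 1 or 2 (0.0593 to 0.0655). Of 8 nuclear-retained noncoding RNAs, listed as a sign of RNA quality, none passed over all genes (*NEAT1* 0.57, SE 0.23, *NORAD* −0.22, SE 0.11), while 1 was higher and 2 were lower adjusted over the list alone (camera adjusted p = 0.809). In all, 14 of the 37 lists passed, 9 upward and 5 downward, and 0 passed with an estimated correlation, where 5 had an unadjusted p-value under 0.05. Fry, which asks only whether a set's own genes move one way, gave 13 lists.

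Of 5909 terms of the deposited annotation, 19 passed, 14 upward and 5 downward, and 0 passed with an estimated correlation (adjusted p = 0.953 with an estimated correlation for each of the 19). In the term 90S preribosome, 5 of 31 genes rose and none fell (camera adjusted p = 0.00461). In tumor necrosis factor-activated receptor activity, 7 of 15 genes rose and none fell (0.0206). Downward, 10 of 40 genes fell in DNA replication initiation (0.0206), 11 of 57 fell and 1 rose in cholesterol biosynthetic process (0.0309) and 5 of 12 fell in homocysteine metabolic process (0.0245). The number of terms was 5 without DMSO replicate 1, 36 without DMSO replicate 2, 12 without DMSO replicate 3 and 0 without S541 replicate 3.

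Of the 302 genes in the authors' deposited table of differential genes (145 up, 157 down), 191 (63.2%) passed here in the same direction, 101 up and 90 down, and 0 of the 262 tested here had the opposite direction. A further 40 were under the filter on low counts. Without S541 replicate 1 or 2 the share was 41.4% or 40.7%, while it was 70.2% with the DESeq2 Wald test and 76.8% with the exact test. Across 15847 genes, which are not independent replicates, both sets of fold changes had a Pearson correlation of 0.999993. Both were computed from the same counts with edgeR, so this correlation and the shared directions follow from that and are not independent evidence. Of the authors' 302 genes, 58 had an adjusted p-value of 0.05 or more in the authors' deposited table. In the refit, of 37 genes that the authors set out in a sheet, 12 rose, 17 fell and 8 did not pass (12 and 24 adjusted over the list alone). How these genes were chosen is not given in the sources used here. In the authors' edgeR comparison all 37 had an unadjusted p-value under 0.05, the highest being 0.0203 for *ARG2*. Their log2 fold changes smallest in size were −0.59 (*PPM1D*) and 0.591 (*PAPSS2*). These values argue for a choice made on these libraries. The counts, including those adjusted over the list alone, are therefore not independent evidence for these genes. Those that fell include the urea-cycle enzymes *CPS1* (948 to 481 CPM, log2 fold change −0.98) and *ASS1* (−0.81), the monoamine oxidase *MAOB* (−1.41) and the placental alkaline phosphatase *ALPP* (3100 to 1118 CPM, −1.47). Those that rose include the polyamine enzymes *ODC1* (0.68), *SAT1* (0.99) and *SMOX* (0.85). These 7 genes were chosen after their values were seen. Calls were not kept for *ASS1* without S541 1 or 2 (0.0763 to 0.0795) and *ODC1* without DMSO 1 or 3 or S541 2 or 3 (0.0521 to 0.0687).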

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

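Robust estimation of the spread and leaving out the 105 genes that differed 4-fold or more within a group were chosen after seeing the data and gave 1353 and 1396 changed genes. No gene of the 1298 changed sign under any alternative. The number of changed genes was 753 with no filter on low counts, where 30834 genes were tested, and 427 against a 1.2-fold change (glmTreat), a stricter null. It was 1790 with the DESeq2 Wald test, 1757 with the exact test and 1254 with limma-voom, of which 366, 455 and 315 changed 2-fold or more. The other scalings gave 1259 (DESeq2 size factors) and 1293 (upper-quartile), and a minimum of 1 CPM in 3 libraries 1301. The share of the authors' calls was 70.2% with DESeq2, 76.82% with the exact test, 61.26% with limma-voom, 53.64% with no filter and 48.68% with glmTreat. Leaving out 1 library gave 349 to 1330 genes, 162 to 376 changed 2-fold or more, 10 to 15 lists, 0 to 36 terms and 40.73 to 62.58% of the authors' calls, with fewer libraries in each fit. Other scalings moved the median log2 fold change of all genes by under 0.1. With an estimated correlation 0 lists and 0 terms passed. Lists with an estimated correlation under the preset one lost their calls too. In the list of endoplasmic reticulum chaperones, that estimate was −0.0327. Its unadjusted camera p-value was 0.00142 with the preset correlation and 0.0234 with the estimated one. For that list, correlation beyond the preset value was therefore not the reason. The estimate was also under the preset value for fatty acid synthesis (−0.00398), mesenchymal transition (−0.00478), epithelial junction (−0.0169) and metallothionein genes (−0.138). A count of 0 lists thus does not by itself show that correlation within the lists ended the calls, and what else was the reason was not tested. Terms numbered 84 with no filter, where the cause was not tested, and 988 with fry, which asks a different question. Of the named genes' calls and values, 1094 kept direction and side of the threshold and 126 kept direction only under the alternatives, with 441 and 215 when a library was left out.

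The replicate numbers are shared between the groups but gave no clear sign of pairing the libraries. Deviations of same-numbered libraries from their group means had correlations across genes of 0.104, −0.0811 and −0.0783. Not every library correlated best with its own number, which cannot exclude that same-numbered libraries were handled together. With the replicate number as a block (replicate block), 392 genes changed, 204 by 2-fold or more, and 12 lists and 9 terms passed, with 50.66% of the authors' calls, 52 of the 99 named genes and fewer residual degrees of freedom. The epithelial (adjusted p = 0.115) and homologous recombination (0.0661) lists were not past the threshold in that fit.

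Reversals were limited to values not past the threshold in the full set, and the cause was not tested. With a library left out, log2 fold changes ranged from −0.02408 to 0.216 for *ATP5F1B*, −0.1059 to 0.01118 for *ATP5F1E*, −0.1115 to 0.02815 for *MRPS34*, −0.02437 to 0.4017 for *PAICS*, −0.2919 to 0.1178 for *RPL37*, −0.2914 to 0.04759 for *RPS18* and −0.1055 to 0.09941 for *TFAM*. Camera adjusted p-values ranged from 0.133 to 0.979 for complex I, 0.209 to 0.825 for complexes II to V, 0.803 to 0.979 for the BCL2 family and caspases, 0.55 to 0.923 for nucleotide synthesis and 0.047 to 0.979 for cytosolic ribosomal proteins. The alveolar and airway list pointed upward with no filter (adjusted p = 0.681). In simulated counts with 200 genes changed, changes of 1.5-fold were mostly below detection.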

Other observations

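Of the tests below, those on swinging genes with no exon overlap, on swinging counts among the ERK output genes, on gene length and expression, on replication genes 1.5-fold apart within a group and on the gap at a minimum under 5 CPM were chosen after the result they bear on was seen. The others were set out before their results were seen.

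Genes that respond to the ERK pathway, a list made after *PHLDA1*, *DUSP4*, *DUSP6* and *ETV4* had been seen to rise, leaned upward in S541. *DUSP6* (3.15 to 10.0 CPM), *ETV5* (log2 fold change 1.19), *SPRY4* (1.15), *ETV4* (0.98) and *EPHA2* (0.44) rose along with them, the last not without DMSO 3 or S541 1, 2 or 3 (adjusted p = 0.0566 to 0.066), whereas *SPRY2* (0.45, adjusted p = 0.0873) and *CCND1* (0.11, adjusted p = 0.44) did not pass (edgeR). As a hypothesis, ERK pathway output may have been higher in S541. The median of the 5 tested members whose values had not been seen, 0.45, lay at percentile 99.67 of 10000 random lists matched on expression, with a camera p = 4.34e-05 and p = 0.0162 with an estimated correlation. Swinging counts argue against themselves as the source, since no tested member differed by more than 1.35-fold between libraries of a group, while no other technical explanation was tested and transcripts alone do not measure the pathway.

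A second pattern is that replication genes were lower while the mitosis list leaned upward. The mitosis list did not pass as a set (camera adjusted p = 0.0506, and 0.479 with an estimated correlation). Neither list holds a gene that differed 4-fold or more within a group (0 of each), so leaving such genes out removed nothing and tested nothing (median −0.318), but without 4 replication genes that differed 1.5-fold or more the median was −0.32. Gene length and expression level do not account for the fall: the median lay at percentile 0 of 10000 random lists matched on both, of which the lowest 5% began at −0.073, while that of the mitosis list, 0.0778, lay at percentile 97.6. RNA quality stays open: the larger of the medians of both quality lists was −0.0729, under the bound set in advance, but 4 of 8 nuclear-retained RNAs and 27 of 74 ribosomal proteins were above 0, and a median over members that go both ways decides nothing. An effect of S541 on the cell cycle may be behind the pattern, as a hypothesis that these libraries cannot separate from RNA quality.

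Some genes swung between libraries of 1 group. Of 11787 genes with a mean of at least 5 CPM, 105 differed 4-fold or more within a group. *MYC* had 10.5, 12.5 and 130 CPM in DMSO and 181, 144 and 14.4 CPM in S541, and *B2M* had 106 CPM in S541 replicate 2 against 517 to 614 CPM elsewhere. Counts simulated with the spread typical of genes at the same expression gave 0.2 such genes on average, which argues against sampling noise at that spread. Extra spread particular to single genes was not simulated. No library held more than 23.1% of the low values, which argues against 1 failed library. Exon overlap with another gene was commoner in swinging genes (75% against 49.7% of others, odds ratio 3.03, 95% interval 1.94 to 4.73), consistent with reads shared between gene models, but 26 of the genes, *MYC* and *B2M* among them, have no exon overlap, so this cannot be the source for all, and no biological explanation was tested.

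Such swings could also fall along the groups by chance. Among genes with a mean of at least 5 CPM, the real grouping had 3 genes (*SERPINE2*, *SPOCD1* and *DHRS2*) with a gap of 4-fold between all libraries of each side, and the highest of the other groupings 2, too close to decide. At a minimum of 2 CPM it was 7 genes against 2, and with no minimum 9 against 4, so the margin depends on the minimum. Among swinging genes, 3 passed the threshold here and 15 are called in the authors' deposited table. Heading that table are the pseudogene *NOC2LP1* (1, 3 and 2 counts in DMSO, 110, 123 and 128 in S541) and *AP002748.4* (0, 0 and 0 counts, against 144, 112 and 80).

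The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For changed genes 1 split, the real one, gave as many as 1298, and the highest of the others gave 2. For genes changed 2-fold or more it was again 1 split, with 325 against 2. For lists it was 1 split, with 14 against 10, so a count of lists with the preset correlation is reached in part by groupings that mix the treatments. For terms, 3 splits gave 19 or more, the highest other 104 (DMSO replicates 1 and 3 with S541 replicate 1 on a side). A count of terms with the preset correlation is thus also reached by groupings that mix the treatments. A structure among the libraries that does not follow the treatment is a possible source that was not tested.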
